A study of Homo sapiens with 6 samples.

How the data were processed

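Cells of the HT-1080 line were treated for 4 h, and RNA was taken from 3 biological replicates with the inhibitor and 3 with DMSO, per the labels and the series design text. Libraries were made with the Ion AmpliSeq Transcriptome panel, which reverse transcribes RNA and amplifies a part of each targeted transcript by multiplex PCR, and were sequenced on an Ion Proton, per the labels' protocols. A count therefore reports the amplified part of a transcript and cannot separate a change of the whole mRNA from a change of an isoform that holds that part. The amplicon positions were not used here.

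The deposited values are counts of reads per gene symbol, whole numbers without normalization, in 1 table per library. HTSeq, DESeq2 1.20.0 and the genome build hg19 are named in the submitters' processing notes, which are given here without the role of each. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. Reads from overlapping genes, antisense partners or near-identical copies, such as histone genes or HSPA1A and HSPA1B, could be split or lost in the counting, so values of such genes are uncertain. The tables held 20683 gene symbols and no rows of unassigned reads. They give no positions, and the reference annotation available is on another build (GRCh38), so no coordinates are printed. Of the symbols, 19694 matched a symbol in the RefSeq gene table of GRCh38.p14, which was used for gene lengths only.

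Groups were taken from the sample titles. The labelled dose of 5 mM may be that of a stock, since the labels state no dilution, or its unit may be wrong, and it is printed as labelled. Library totals ran from 7644478 to 15336351 counts. For a gene without a count, the floor of 3 counts corresponds to 0.196 to 0.392 CPM. PCR reads without molecular identifiers are not independent molecules, so such floors and bounds cover counting error only. Libraries of a group were compared by a chi-square over genes with at least 20 summed counts. Each pair differed by more than sampling noise (chi-square per degree of freedom from 9.32 to 14.7), as separately amplified libraries of 1 RNA would too, so each library was counted as 1 replicate because the series design describes biological replicates.

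Counts were analysed in R 4.3.3 with edgeR 4.0.16. The low-count filter of edgeR (filterByExpr with the group) left 11391 genes with 99.924% of the counts, and 4605 of the genes left out had no count in any library. TMM scaling factors ran from 0.9735 to 1.047. Group differences were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, inhibitor minus DMSO, without covariates), and p was adjusted by Benjamini-Hochberg, with a call at an adjusted p under 0.05. The words rose and fell refer to such calls. Normalised counts (CPM) are counts scaled to a library of 1000000 counts, with the TMM factors, and are given as mean ± SD over 3 libraries. log2 fold changes are given ± SE, taken as the fold change divided by the square root of the test's F. A fold against a group without counts is given as a bound, with 3 counts over the group in its place.

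Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, for lists with at least 5 tested members, and adjusted over the 34 such lists. The lists written after the result was seen were adjusted apart, over the 4 of them that were tested. Camera with an estimated correlation was run beside it. Calls of members were also adjusted over the list alone. The 39 lists, the tests and the rule for naming genes were fixed before the data were examined. The rule names the 10 genes that rose and the 10 that fell with the largest absolute log2 fold change among called genes with a mean of at least 5 CPM and no overlap between groups. It adds IRAK1, IRAK2, IRAK3, IRAK4 and MYD88, and from each list up to 4 called members with the largest absolute log2 fold change or, where none was called, up to 2 with the smallest p. Genes outside the rule are marked where they are named. Some genes that the rule selects are not reported here. Library totals, detected genes and the share of the 20 most abundant genes were compared by two-sided exact permutation tests. Principal components used log2 CPM with a prior count of 2.

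Alternatives were DESeq2 size factors, upper-quartile scaling and library totals alone, no count filter, a minimum mean of 10 CPM, a replicate block, DESeq2 1.42.0, limma voom, a test against a fold of 1.2, libraries thinned to the smallest total, the 20 most abundant genes left out, and each library left out in turn. The procedure was tested on simulated counts with the means and depths of these libraries. In that simulation of the comparison, on 11296 genes, 54% of genes with a log2 change of 0.5 were recovered, 93.88% at 1, 95.83% at 1.5 and 100% at 2, and 10 calls (5.587%) were false. The simulated changes, drawn as rises and falls in equal number, covered 50, 49, 48 and 50 genes at these sizes. That is a far smaller share than the 20.2% of genes called in the data. The shares recovered and false may therefore differ in the data. Without a simulated effect, 0 genes and 0 lists were called. Counts of each gene were drawn independently in a single run, so this does not show how often camera calls lists of correlated genes. Where a search of 3' untranslated regions (3' UTRs) is reported, the longest 3' UTR of each gene in GENCODE release 29 was used. Tests of the closing section were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Permutation and bootstrap tests of that section drew genes as if independent, so their p and intervals do not measure the spread between cultures.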

Results

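Messenger RNA was counted in HT-1080, a human fibrosarcoma cell line, after 4 h with a compound that the series describes as an inhibitor of IRAK4, or with its solvent DMSO. IRAK4 is a kinase that acts with the adaptor MYD88 downstream of interleukin-1 and Toll-like receptors, on the way to the transcription factor NF-kB. The compound is known here by the code SLV-8472-01 alone, and its labelled dose was 5 mM. The label does not say whether that is the concentration on the cells or that of a stock, and its unit could not be checked, so the dose is given as labelled. Control cells had 0.1% DMSO. Each group had 3 libraries, described in the series design as biological replicates. The inhibitor libraries held 11427779, 9449982 and 7644478 counts and the DMSO libraries 15336351, 14805241 and 12003104. The mean total of the inhibitor group was 0.677 times that of the DMSO group (two-sided exact permutation test, p = 0.1, the smallest p that 3 against 3 allows). Counts were found for 13830 ± 179 genes (SD, n = 3) in the inhibitor group and 14120 ± 118 in the DMSO group (exact permutation p = 0.2). The 20 most abundant genes of each library took 13.92% ± 0.164 of its counts in the inhibitor group and 12.53% ± 0.693 in the DMSO group (exact permutation p = 0.1).

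The comparison asked which genes differ in HT-1080 cells after 4 h with the inhibitor. The lists of ATF4 and p53 target genes and of output genes of the ERK pathway were called upward with the inhibitor, and that of DNA replication genes downward. A list call does not show which factor drove its genes, and SESN2 is in both the ATF4 and the p53 list. Of 11391 genes tested, 2298 (20.2%) changed, of which 1130 rose and 1168 fell (edgeR quasi-likelihood test, adjusted p under 0.05). With library totals alone as the scaling, 831 rose and 1714 fell. That scaling shifted the median log2 fold change of all genes by -0.0716. Most changes were small, with a median absolute log2 fold change of 0.535 among the changed genes. At least a 2-fold difference was found for 185 genes that rose and 89 that fell. Without DMSO replicate 2 the count of changed genes was 1405. The groups did not overlap in normalised counts for 4140 tested genes (36.3%), where a chance order of the libraries gives 10% for a single gene. Genes vary together, so this share is a description and not a test. The first principal component held 52.5% of the variance and separated the groups. The second held 16.8% and set inhibitor replicate 3, the library with the fewest counts, at -23.6, apart from the other inhibitor libraries at 13.2 and 9.97.

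Of the upstream pathway, IRAK3, IRAK4 and MYD88 had few or no counts. Low counts can come from little mRNA or from poor amplification of the targeted part, which these data cannot separate. IRAK4 mRNA was at 1.11 ± 0.28 CPM (SD, n = 3) with the inhibitor and 0.80 ± 0.31 with DMSO (adjusted p = 0.495). IRAK1, a kinase that IRAK4 phosphorylates, was at 27.7 ± 2.47 and 27.4 ± 2.21 CPM (adjusted p = 0.924). IRAK2, a related kinase, rose by a log2 fold change of 0.59 ± 0.17 (SE), from 8.47 ± 1.47 to 12.7 ± 1.69 CPM (adjusted p = 0.0159). That call was lost without inhibitor replicate 1 (adjusted p = 0.102), without DMSO replicate 1 (0.0813), without DMSO replicate 3 (0.051) and in libraries thinned to the smallest total (0.0599). IRAK3 had 0 counts in every library, which allows up to 0.196 to 0.392 CPM depending on the library. MYD88 had 4, 2 and 3 counts with the inhibitor and 0, 3 and 3 with DMSO, too few to test. Of 26 tested components of interleukin-1 and Toll-like receptor signalling, 3 rose and 7 fell, and the same numbers passed when adjusted over the list alone. Those that rose were IRAK2 and the IkB kinase subunit genes IKBKG (0.72 ± 0.20) and IKBKB (0.56 ± 0.13), and PELI3 fell by 0.70 on the log2 scale. None of these named genes was called in the edgeR test against a fold of 1.2. Its adjusted p was 0.0959 for IRAK2, 0.0593 for IKBKG, 0.0534 for IKBKB and 0.0616 for PELI3. The list as a whole was not called (camera adjusted p = 0.818; median log2 fold change 0.0551, and from 0.0336 without inhibitor replicate 1 to 0.13 without inhibitor replicate 2). The sign of the test was downward, and upward without inhibitor replicate 2 or with no filter beyond 1 count. The number that fell was 4 without inhibitor replicate 2 and 4 without DMSO replicate 2.

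The largest rise among genes with at least 5 CPM was in CHAC1, a glutathione-degrading enzyme of the stress response, from 2.13 ± 0.41 to 34.7 ± 8.79 CPM (log2 fold change 4.04 ± 0.20, SE, adjusted p = 3.72e-12). The neutrophil-attracting chemokine genes CXCL3 and CXCL8 rose by 3.22 ± 0.22 and 2.47 ± 0.18. The stress genes SESN2 (2.45 ± 0.11), DDIT4 (2.31 ± 0.13) and TRIB3 (2.25 ± 0.11) also rose, and TRIB3 reached 471 ± 52.2 CPM from 99.2 ± 6.04. The remaining genes of the 10 largest rises were RAB39B (2.71 ± 0.21), TAGLN3 (2.24 ± 0.12), the interferon-induced IFIT2 (2.21 ± 0.17) and SLFN5 (2.14 ± 0.12). The largest fall was in FAM111B, from 61.2 ± 3.96 to 14.01 ± 1.42 CPM (log2 fold change -2.13 ± 0.12). SERTAD4 (-1.75 ± 0.23), WSB1 (-1.63 ± 0.18) and the heat shock protein gene HSPA1B (-1.59 ± 0.14) followed. CCNE2, which encodes cyclin E2 (-1.58 ± 0.15), and the phosphatase gene CDC25A (-1.41 ± 0.14), both in the DNA replication list, were also among the 10 largest falls. ZNF367 (-1.54 ± 0.12), WDR76 (-1.49 ± 0.14), the replication licensing inhibitor GMNN (-1.44 ± 0.19) and ATAD5 (-1.41 ± 0.18) completed that set. In each of these 20 genes every inhibitor library lay on the same side of every DMSO library, as the rule for naming them required.

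**Figure D1:**
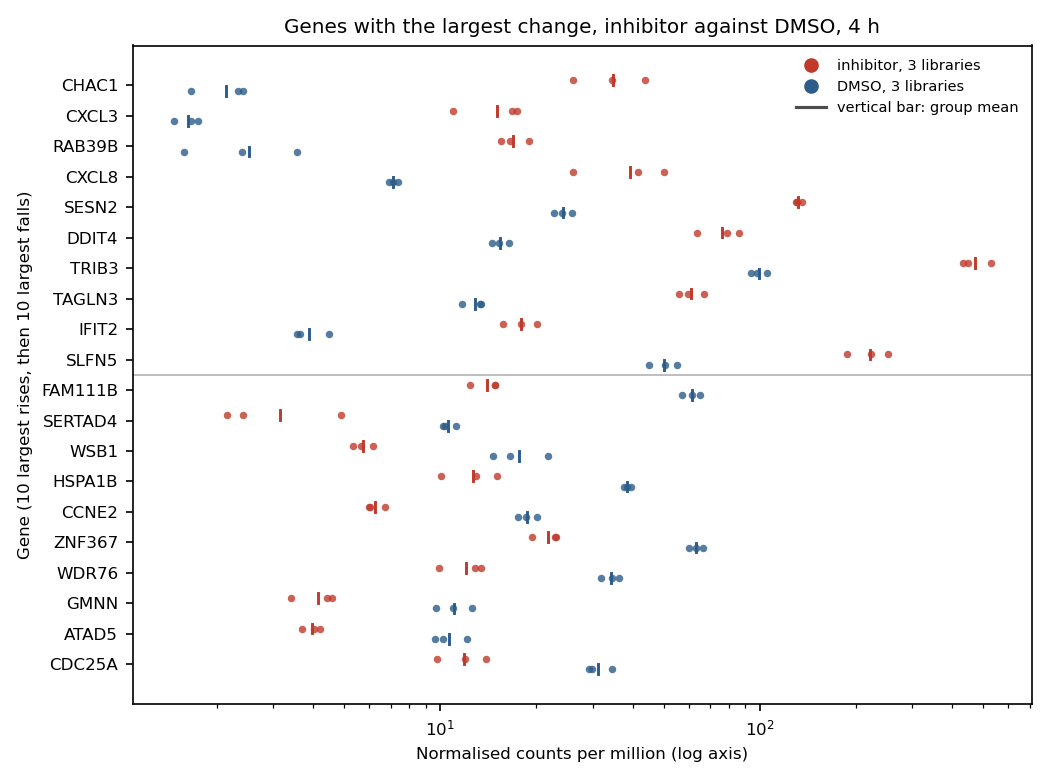
Normalised counts (CPM) on a log axis for the 10 genes with the largest rise and the 10 with the largest fall, with a point for each of the 3 libraries per group and a vertical bar for the group mean. CHAC1 lies at 34.7 CPM on average with the inhibitor and 2.13 with DMSO, and FAM111B at 14.01 and 61.2.

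Of the 39 gene lists fixed before the data were examined, 34 had at least 5 tested members, and camera called 22 of them, 17 upward and 5 downward. With an estimated correlation between genes, 4 lists were called. These were the ATF4, p53 and ERK lists upward and the DNA replication list downward. That version of camera gave larger p also where the estimate lay under the preset 0.01. The hypoxia and glycolysis list, estimated at -0.00601, had a camera adjusted p = 0.00927 with the preset and 0.152 with the estimate. The loss of calls therefore does not measure correlation between genes alone. Several lists share members, so their results are not independent of each other.

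**Figure D2:**
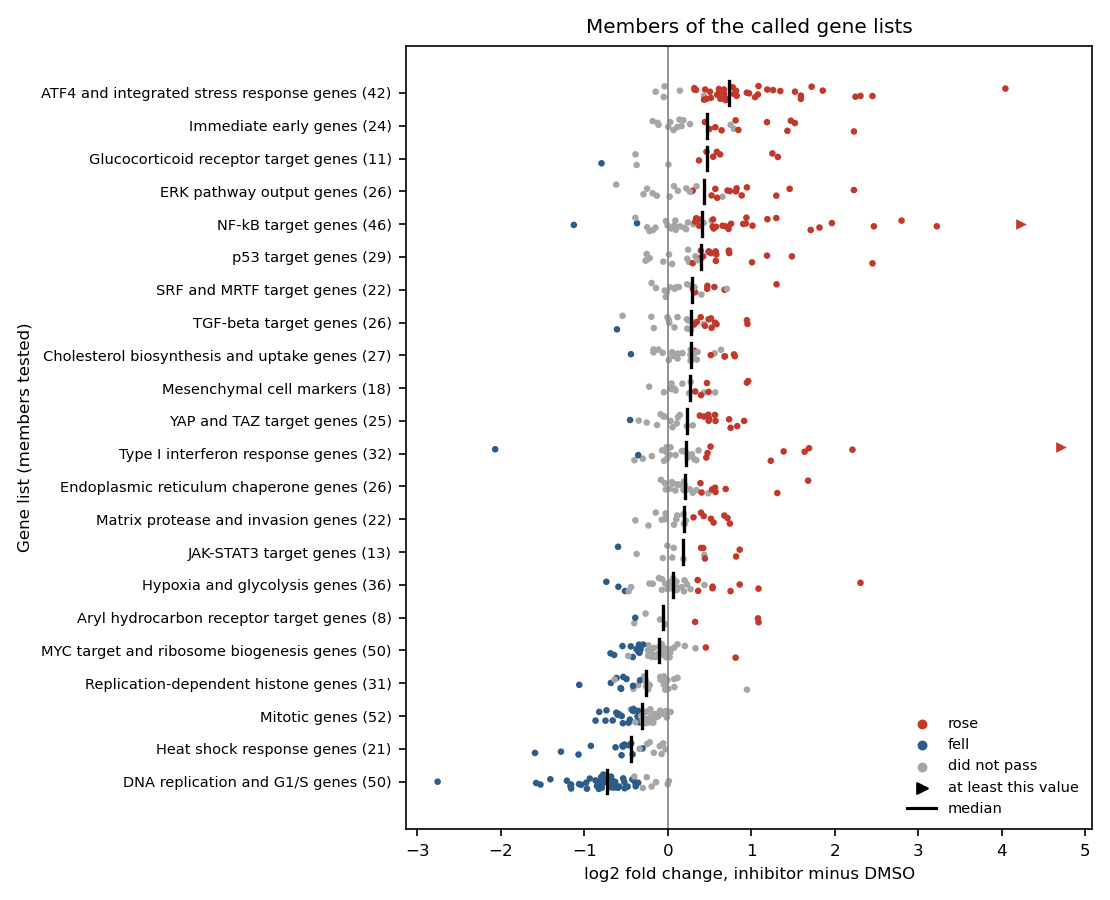
log2 fold change (inhibitor minus DMSO) of each tested member of the 22 called lists, with the median as a black bar and triangles for genes without a count in the DMSO group, drawn at their lower bound. The medians run from 0.734 for the ATF4 list to -0.727 for the DNA replication list.

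Target genes of ATF4, the transcription factor of the integrated stress response, rose most widely. Of 42 tested, 37 rose and 0 fell (38 rose when adjusted over the list alone), with a median log2 fold change of 0.734 (camera adjusted p = 1.92e-49; adjusted p = 0.0285 with an estimated correlation). CHAC1, SESN2, DDIT4 and TRIB3 led this list. Of 29 p53 target genes, 17 rose and 0 fell, and 19 rose and 1 fell when adjusted over the list alone (median 0.394, camera adjusted p = 2.85e-11; adjusted p = 0.0285 with an estimated correlation). After SESN2, which the ATF4 list also holds, the largest rises there were in the secreted factor GDF15 (1.48 ± 0.11), the antiproliferative BTG2 (1.19 ± 0.14) and the cell death gene PMAIP1 (1.01 ± 0.13). The number of p53 targets that rose was 11 without DMSO replicate 2, and 2 fell with library totals as the scaling. Of 26 genes of the endoplasmic reticulum chaperone list, which also holds genes that are not chaperones, 8 rose and 0 fell, and 10 rose when adjusted over the list alone (median 0.207, camera adjusted p = 1.24e-05). That list had an adjusted p = 0.271 with an estimated correlation, and 4 of its genes rose without DMSO replicate 2. Its median was 0.352 without DMSO replicate 1. The largest rises of that list were in genes that do not encode chaperones. XBP1, a transcription factor of the unfolded protein response, rose from 60.6 ± 2.12 to 194 ± 44.9 CPM (1.68 ± 0.13), HERPUD1 by 1.31 ± 0.14 and SYVN1 by 0.69 ± 0.13. The chaperone gene HYOU1 rose by 0.57 ± 0.15, but its groups overlapped. Its call was lost with DESeq2 (adjusted p = 0.142), without DMSO replicate 2 (0.0807) and without DMSO replicate 3 (0.0584).

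Of 46 NF-kB target genes tested, 25 rose and 2 fell, and 26 rose and 2 fell when adjusted over the list alone. The median log2 fold change was 0.406, also with CXCL10 set at its bound (camera adjusted p = 3.81e-14; adjusted p = 0.0603 with an estimated correlation). CXCL10, a chemokine gene, had 19, 11 and 8 counts with the inhibitor and 0 in each DMSO library. It was at least 18.7-fold higher, against a floor of 3 counts over the DMSO group. The chemokine gene CCL5 rose by 2.80 ± 0.41, from 0.40 ± 0.31 to 2.94 ± 0.37 CPM. The 2 genes that fell, TRAF2 and CSF1, are named after their values were seen, and 1 fell without inhibitor replicate 2 or without DMSO replicate 1. With a minimum mean of 10 CPM, under which fewer genes are tested, 16 NF-kB targets rose.

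Of 32 type I interferon response genes, 9 rose and 2 fell, also when adjusted over the list alone (median 0.222, camera adjusted p = 0.00125; adjusted p = 0.187 with an estimated correlation). The antiviral gene RSAD2 had 26, 19 and 8 counts with the inhibitor and 0 in each DMSO library, and was at least 26.1-fold higher against the same floor. The median was the same with RSAD2 at that bound. IFIT2 and OASL (1.69 ± 0.38) rose as well, and PARP9 fell by 2.07 on the log2 scale at under 2 CPM. The PARP9 call was lost without inhibitor replicate 1 (adjusted p = 0.079), inhibitor replicate 2 (0.0732) or DMSO replicate 3 (0.0595). The other gene that fell, DTX3L, is named after its value was seen. No gene of the list fell without inhibitor replicate 1 or in thinned libraries, and 1 fell without any other single library. The median was 0.138 without inhibitor replicate 1. The number that rose was 3 with a minimum of 10 CPM, 4 in libraries thinned to the smallest total and 5 without DMSO replicate 3. Of 13 JAK-STAT3 target genes, 5 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (median 0.186, camera adjusted p = 0.038; adjusted p = 0.348 with an estimated correlation). The angiogenic factor VEGFA rose by 0.86 ± 0.11 and the receptor gene IL4R fell by 0.60 on the log2 scale. The call of the list was lost without inhibitor replicate 1 (camera adjusted p = 0.108, with 3 genes that rose), without DMSO replicate 2 (0.0771) and with a minimum of 10 CPM (0.0502).

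Immediate early genes respond within minutes to growth factors and stress. Of 24 tested, 11 rose and 0 fell, and 12 rose when adjusted over the list alone (median 0.471, camera adjusted p = 8.35e-08; adjusted p = 0.187 with an estimated correlation). EGR1 rose from 1.29 ± 0.32 to 6.09 ± 1.57 CPM (2.23 ± 0.27), and FOSB (1.52 ± 0.34), ATF3 (1.47 ± 0.22) and NR4A1 (1.43 ± 0.34) rose as well. With a minimum of 10 CPM, which left 17 genes, 7 rose and the median was 0.199. Of 26 output genes of the ERK kinase pathway, 13 rose and 0 fell, and 15 rose and 3 fell when adjusted over the list alone (median 0.433, camera adjusted p = 1.83e-10; adjusted p = 0.0285 with an estimated correlation). The growth factor gene HBEGF rose from 167 ± 6.55 to 460 ± 14.8 CPM (1.46 ± 0.10), and the cytokine LIF by 1.30 ± 0.13. Of the ERK output genes, 3 fell with library totals as the scaling, and 1 fell without any one of inhibitor replicates 1 and 3 and DMSO replicate 3. Of 11 glucocorticoid receptor target genes, 7 rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone (median 0.462, camera adjusted p = 0.00125; adjusted p = 0.187 with an estimated correlation). The phosphatase gene DUSP1 (1.32 ± 0.11) and TSC22D3 (1.25 ± 0.14) rose, and FKBP5, a classical target of the receptor, fell by 0.80 on the log2 scale. The number that rose was 4 without inhibitor replicate 1 and 4 without DMSO replicate 2, and 2 fell without DMSO replicate 1.

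Lists of YAP and TAZ, SRF and MRTF, TGF-beta, matrix protease and mesenchymal genes were also called upward, none of them with an estimated correlation. Of 25 YAP and TAZ target genes, 11 rose and 1 fell, and 12 rose and 2 fell when adjusted over the list alone (median 0.225, camera adjusted p = 5.73e-04; adjusted p = 0.232 with an estimated correlation). ANKRD1 (0.91 ± 0.12), DLC1 (0.75 ± 0.10) and AMOTL2 (0.73 ± 0.10) were among those that rose, and AMOTL1, named after its value was seen, fell, while 0 fell without DMSO replicate 2 and 2 without inhibitor replicate 1. Of 22 SRF and MRTF target genes, 7 rose and 0 fell, and 9 rose when adjusted over the list alone (median 0.289, camera adjusted p = 5.73e-04; adjusted p = 0.187 with an estimated correlation). The median was 0.169 without inhibitor replicate 1. The adhesion protein gene VCL rose by 1.30 ± 0.14 and the smooth muscle actin gene ACTA2 by 0.68 ± 0.11. Of 26 TGF-beta target genes, 11 rose and 1 fell, and 11 rose and 2 fell when adjusted over the list alone (median 0.275, camera adjusted p = 5.73e-04; adjusted p = 0.271 with an estimated correlation). BHLHE40 and the transcription factor SNAI2 rose by 0.95 ± 0.11 and 0.95 ± 0.12. SMAD6 fell by 0.61 on the log2 scale, a call lost without any one of inhibitor replicates 2 and 3 and DMSO replicates 2 and 3 (adjusted p from 0.0536 to 0.118). Of 22 matrix protease and invasion genes, 8 rose and 0 fell, also when adjusted over the list alone (median 0.191, camera adjusted p = 0.00125; adjusted p = 0.187 with an estimated correlation). The plasminogen activator gene PLAT rose by 0.74 ± 0.11 and the urokinase receptor gene PLAUR by 0.71 ± 0.11. Of 18 mesenchymal markers, 6 rose and 0 fell, also when adjusted over the list alone (median 0.263, camera adjusted p = 0.00184; adjusted p = 0.152 with an estimated correlation). The collagen gene COL6A3 rose by 0.96 ± 0.14. Without DMSO replicate 2, 7 YAP and TAZ targets and 5 matrix protease genes rose, and without inhibitor replicate 1, 3 mesenchymal markers rose.

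Genes of DNA replication and the G1/S transition fell most widely. Of 50 tested, 43 fell and 0 rose, and 45 fell when adjusted over the list alone (median -0.727, camera adjusted p = 5.03e-39; adjusted p = 0.0383 with an estimated correlation). The transcription factor genes E2F2 (-2.76 ± 0.41) and E2F8 (-1.53 ± 0.26) fell together with CCNE2 and CDC25A. E2F2 was at 0.41 ± 0.14 CPM with the inhibitor and 2.76 ± 0.58 with DMSO. Of 52 mitotic genes, 20 fell and 0 rose, and 26 fell when adjusted over the list alone (median -0.313, camera adjusted p = 3.25e-09; adjusted p = 0.187 with an estimated correlation). The kinesin genes KIF11 (-0.87 ± 0.14) and KIF20B (-0.82 ± 0.14) and the kinase gene AURKA (-0.75 ± 0.14) had the largest falls. The number of mitotic genes that fell was 11 without inhibitor replicate 1 and 12 without DMSO replicate 2. Of 31 replication-dependent histone genes, 9 fell and 0 rose, and 11 fell when adjusted over the list alone (median -0.26, camera adjusted p = 2.11e-04; adjusted p = 0.271 with an estimated correlation). HIST1H3A fell by 1.06 on the log2 scale. Histone genes are near-identical copies, so the counts of single members are uncertain, and 15 fell with library totals as the scaling, while 1 rose without DMSO replicate 3.

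Heat shock genes encode chaperones and proteins that act with them. Of 21 tested, 13 fell and 0 rose, and 14 fell when adjusted over the list alone (median -0.44, camera adjusted p = 9.85e-12; adjusted p = 0.0921 with an estimated correlation). HSPA8, the constitutive HSP70 gene, fell from 2758 ± 94.0 to 1313 ± 80.1 CPM (-1.07 ± 0.10), and its cochaperone gene DNAJA1 fell by 0.92 on the log2 scale. HSPA1A and HSPA1B fell by 1.28 and 1.59 on the log2 scale, but are near-identical, so reads could be split between them. Of 50 MYC target and ribosome biogenesis genes, 13 fell and 2 rose, and 13 fell and 3 rose when adjusted over the list alone (median -0.107, camera adjusted p = 0.0119; adjusted p = 0.232 with an estimated correlation). GNL3, a nucleolar GTPase gene, fell by 0.64 on the log2 scale, while MYC itself rose by 0.81 ± 0.11. The list was no longer called with a minimum of 10 CPM (camera adjusted p = 0.0502). The number that fell was 8 without DMSO replicate 2 and 7 without DMSO replicate 3. Of 59 cytosolic ribosomal protein genes, 3 rose and 0 fell, and 0 passed when adjusted over the list alone (median 0.0811, camera adjusted p = 0.111). The 3 were RPLP2, RPL28 and RPL3, and none of these calls was kept with library totals as the scaling or without DMSO replicate 2. With upper-quartile scaling 7 rose, and 5 rose without inhibitor replicate 3 and 1 without DMSO replicate 3. Without inhibitor replicate 1 the list was called upward (median 0.105, camera adjusted p = 0.0242). With all libraries its adjusted p was 0.425 with an estimated correlation, which was not run without single libraries, and its median was 0.052 without inhibitor replicate 2 and 0.0439 without DMSO replicate 2.

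Among metabolic lists, 6 of 27 genes of cholesterol synthesis and uptake rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (median 0.274, camera adjusted p = 0.00128; adjusted p = 0.187 with an estimated correlation). INSIG1, a sterol-sensing regulator of the pathway, rose by 0.79 ± 0.15, and the sterol oxidase gene MSMO1 by 0.68 ± 0.10. TMEM97, named after its value was seen, fell, but 0 fell without inhibitor replicate 1 or without DMSO replicate 2. Of 36 hypoxia and glycolysis genes, 8 rose and 3 fell, and 8 rose and 5 fell when adjusted over the list alone (median 0.0618, camera adjusted p = 0.00927; adjusted p = 0.152 with an estimated correlation). DDIT4, STC2 (1.09 ± 0.11), VEGFA and INSIG2 (0.75 ± 0.17) led the list, and the ATF4 list also holds DDIT4 and STC2. The glycolytic gene ALDOA, with PFKFB4 and EGLN1, fell, all named after their values were seen. The median of this list was -0.00977 with library totals as the scaling, under which 5 fell, and 0.11 and 0.108 without inhibitor replicate 3 and DMSO replicate 3, and 1 fell without inhibitor replicate 1, without DMSO replicate 2 or with a minimum of 10 CPM. Of 8 aryl hydrocarbon receptor target genes, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0442; adjusted p = 0.254 with an estimated correlation). The median was -0.0617, against the upward sign of the test, and ran from -0.242 without inhibitor replicate 1 to 0.117 without inhibitor replicate 2 when single libraries were left out, with -0.016 without DMSO replicate 1 and -0.00306 without inhibitor replicate 3. With a minimum of 10 CPM, which left 5 genes, it was 0.338 (camera adjusted p = 0.00261). STC2 and the amino acid transporter gene SLC7A5 (1.08 ± 0.11), both also in the ATF4 list, and NFE2L2 rose, and NQO1 fell by 0.39 on the log2 scale. The call of this list was lost without inhibitor replicate 1 (camera adjusted p = 0.0851), DMSO replicate 2 (0.0835) or DMSO replicate 3 (0.0693), and with no filter beyond 1 count (0.0522). NFE2L2 was not called with library totals as the scaling (adjusted p = 0.077) or without any one of inhibitor replicates 2 and 3 and DMSO replicates 1 and 2 (adjusted p from 0.0634 to 0.155), and NQO1 was not called without DMSO replicate 2 (adjusted p = 0.0796). Of 14 fatty acid synthesis genes, SCD alone rose (0.37 ± 0.10), also when adjusted over the list alone (list median 0.0614, and -0.006 without inhibitor replicate 3; camera adjusted p = 0.505), and it was not called without DMSO replicate 2 (adjusted p = 0.0688), while 2 genes of the list rose without inhibitor replicate 3 or without DMSO replicate 3. Of 7 LXR target genes 0 rose and 0 fell, also when adjusted over the list alone (median -0.209, and 0.0299 over 8 genes with no filter beyond 1 count; camera adjusted p = 0.732), and LPCAT3 and SREBF1 had the smallest p (adjusted p = 0.077 and 0.113). LPCAT3 was called with library totals as the scaling (log2 fold change -0.37, adjusted p = 0.0298), and SREBF1 without inhibitor replicate 3 (0.41, adjusted p = 0.0304) and without DMSO replicate 3 (0.44, adjusted p = 0.0411). Of 25 NRF2 target genes, 1 rose and 2 fell, also when adjusted over the list alone (median 0.0293, and from -0.0294 without inhibitor replicate 1 to 0.0523 without inhibitor replicate 3; camera adjusted p = 0.965). SLC7A11, also an ATF4 list member, rose by 0.69 ± 0.11. The number that fell was 1 without inhibitor replicate 1 and 0 without DMSO replicate 2, and 2 rose without inhibitor replicate 3.

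The other fixed lists were not called with the main settings. Of 23 FOXO and PI3K-repressed genes, 3 rose and 4 fell, also when adjusted over the list alone (median 0.0178, and from -0.0746 without inhibitor replicate 2 to 0.0758 without DMSO replicate 3; camera adjusted p = 0.739). TXNIP fell by 1.01 and BCL2L11 by 0.82 on the log2 scale. With a minimum of 10 CPM, 2 fell. Of 38 lysosome and autophagy genes, 5 rose and 4 fell, and 5 rose and 5 fell when adjusted over the list alone (median 0.079, and 0.044 without inhibitor replicate 3; camera adjusted p = 0.477), with a rise of CTSD by 0.52 ± 0.10. The number that rose was 3 without DMSO replicate 2, and the number that fell 2 without inhibitor replicate 2 or without DMSO replicate 1. Of 10 Wnt target genes, MYC and CD44 (0.53 ± 0.14) rose and 0 fell, also when adjusted over the list alone (median -0.107, and -0.048 without inhibitor replicate 2, against an upward sign of the test, camera adjusted p = 0.732), while 1 fell without inhibitor replicate 1. Of 15 circadian clock genes, 6 rose and 2 fell, also when adjusted over the list alone (median 0.168, camera adjusted p = 0.116), with a rise of ARNTL by 0.76 ± 0.18. The number that rose was 3 without DMSO replicate 1, and the number that fell 0 without DMSO replicate 2 and 1 without any one of the inhibitor replicates or DMSO replicate 3. With a minimum of 10 CPM, which left 8 genes, the list was called upward (median 0.26, camera adjusted p = 0.0171), while an estimated correlation, run with the main settings alone, gave an adjusted p = 0.272. Of 25 short-lived transcription regulators, 7 rose and 2 fell, and 8 rose and 3 fell when adjusted over the list alone (median -0.0254, and from -0.0185 without inhibitor replicate 2 to 0.0597 without inhibitor replicate 1; camera adjusted p = 0.111), with a rise of HEXIM2 by 0.84 ± 0.18. The 2 that fell were BRD2 and HEXIM1, named after their values were seen, and 1 fell without any one of inhibitor replicate 2 and DMSO replicates 2 and 3. Of 8 Notch target genes, 3 rose and 1 fell, also when adjusted over the list alone (median 0.0268, camera adjusted p = 0.0665), with a rise of the ligand gene JAG1 from 142 ± 9.71 to 327 ± 17.9 CPM and a fall of CCND3 by 0.69 on the log2 scale. In thinned libraries, with 7 genes tested, the Notch list was called upward (median 0.237, camera adjusted p = 0.0255), while an estimated correlation with the main settings gave an adjusted p = 0.271. Its median ran from -0.154 without DMSO replicate 1 and -0.127 without DMSO replicate 3 to 0.171 without inhibitor replicate 2, so it gives no direction. Of 14 BCL2 family genes, 4 rose and 3 fell, also when adjusted over the list alone (median 0.0271, with -0.0757 without inhibitor replicate 1 and -0.0143 without DMSO replicate 1; camera adjusted p = 0.496). PMAIP1 and BCL2A1 (0.95 ± 0.14) rose and BCL2 fell by 0.84 on the log2 scale. The BCL2 call was lost without DMSO replicate 3 (adjusted p = 0.0684), where 1 gene of the list fell.

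Markers of other cell types had few tested members, too few for camera. Of 20 epithelial markers 2 were tested, of 18 neural and melanocyte markers 3, and of 14 hepatocyte markers 0, and none of these was called, also when adjusted over the list alone. KRT15 was at 32.4 ± 2.18 and 27.3 ± 2.80 CPM (adjusted p = 0.149), and the tubulin gene TUBB3 at 122 ± 3.73 and 145 ± 8.10 CPM (adjusted p = 0.0789). TUBB3 was called with library totals as the scaling (log2 fold change -0.32, adjusted p = 0.0257). Of 26 blood cell markers 4 were tested, and LCP1 (0.40 ± 0.10) and CD68 (0.32 ± 0.10) rose, also when adjusted over the list alone. LCP1 was at 209 ± 6.37 CPM with the inhibitor and 159 ± 6.45 with DMSO. The CD68 call was lost with library totals as the scaling (adjusted p = 0.0812) and without any one of inhibitor replicates 1 and 2 and DMSO replicates 2 and 3 (adjusted p from 0.0652 to 0.179). Of 15 endothelial markers 4 were tested, and ROBO4 (0.72 ± 0.13) and TIE1 (0.42 ± 0.11) rose, also when adjusted over the list alone. TIE1 was not called without DMSO replicate 2 (adjusted p = 0.053).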

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

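The reading of the gene lists without inhibitor replicate 3 and the list tests with upper-quartile scaling, without a filter, with thinned libraries and without the 20 most abundant genes were chosen after the result was seen. Tested against a fold of 1.2, 829 genes changed, of which 449 rose and 380 fell, and 1469 of the main calls were lost. Calls lost in this test include CLK2 (adjusted p = 0.253), SMAD6 (0.0998), SCD (0.286) and CD68 (0.471). Apart from the receptor signalling genes, the lost calls given above and below for single genes leave this stricter test out. With 1 library left out, between 1405 (without DMSO replicate 2) and 2246 genes changed, between 684 and 1133 rose and between 721 and 1113 fell, with fewer samples in each fit. In the other settings between 1785 (minimum of 10 CPM) and 2545 (library totals alone) genes changed. DESeq2 called 1983 and limma voom 2267, and 1988 were called in libraries thinned to the smallest total. None of the genes called in the main comparison had the other sign in any of these settings. With an estimated correlation 4 lists were called in place of 22, and between 20 and 23 in the other settings. The JAK-STAT3 list was called in 11 of 14 settings, the aryl hydrocarbon receptor list in 10, the MYC list in 13, and each other called list in all 14, always in the same direction. Over 152 named genes there were 2538 values under alternatives, of which 2408 kept the side of the threshold, 126 were no longer called, 4 were newly called and 0 were reversed. Replicate numbers are shared by the groups, but same-numbered libraries did not deviate together (correlations of 0.032, -0.017 and 0.0069), so they share only a number. With the replicate block 2223 genes changed, 2155 of them shared with the fit without it, and no inhibitor library correlated best with the DMSO library of its own number.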

Other observations

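The lists of SR protein, CLK kinase, hnRNP, core spliceosome and homologous recombination genes, and the tests of NF-kB members in no other list, of matched random lists, of replication against mitotic genes and of immediate early and short-lived regulator genes, were chosen after the result was seen. The camera p of these lists were adjusted over the 4 of them that were tested, SR protein, hnRNP, core spliceosome and homologous recombination, not over the fixed lists. SR proteins are splicing factors, and CLK kinases phosphorylate them. Of 13 SR protein genes, 9 fell and 0 rose (median log2 fold change -0.657, camera adjusted p = 1.43e-09; adjusted p = 0.0107 with an estimated correlation). SRSF10 fell from 34.4 ± 1.13 to 15.0 ± 1.74 CPM (SD, n = 3 each; log2 fold change -1.20 ± 0.13, SE), and SRSF3 and SRSF6 fell by 0.86 and 0.74 on the log2 scale. Each of the 4 CLK genes rose, with CLK4 from 2.74 ± 0.18 to 10.5 ± 0.92 CPM (1.92 ± 0.19), CLK1 by 1.42 ± 0.12, CLK3 by 1.17 ± 0.13 and CLK2 by 0.40 ± 0.12. The CLK2 call was lost with library totals as the scaling (adjusted p = 0.0533) and without any one of inhibitor replicates 1 and 2 and DMSO replicates 1 and 3 (adjusted p from 0.0536 to 0.0766). Of 20 hnRNP genes, 2 rose and 6 fell (median -0.135, camera adjusted p = 0.117), and of 34 core spliceosome genes, 2 rose and 7 fell (median -0.112, camera adjusted p = 0.063). The number of hnRNP genes that fell was 3 without inhibitor replicate 3 or DMSO replicate 1 and 2 without DMSO replicate 3, and their number that rose 1 without DMSO replicate 2. Their median was -0.0465 without inhibitor replicate 3. Of the core spliceosome genes, 4 fell without inhibitor replicate 1 or DMSO replicate 1, and the number that rose was 0 with library totals as the scaling or without any one of inhibitor replicate 2 and DMSO replicates 2 and 3, and 1 without inhibitor replicate 3 or DMSO replicate 1. Their median was -0.0658 without inhibitor replicate 1.

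Genes of homologous recombination and the Fanconi pathway repair broken and crosslinked DNA. Of 32 tested, 14 fell and 1 rose (median -0.396, camera adjusted p = 6.38e-08; adjusted p = 0.104 with an estimated correlation). RAD54B (-1.23 ± 0.23), the exonuclease gene EXO1 (-1.21 ± 0.14), which the replication list also holds, and XRCC2 (-1.19 ± 0.14) fell. FANCC, named after its value was seen, rose.

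Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many as 2298 genes. The highest of the other splits called 0 (edgeR, with 490 at an unadjusted p under 0.05, against 3801 for the real split). Each other split mixes both treatments, so a difference between them adds to the spread within groups and lowers the calls. The 0 therefore does not show how many genes an arbitrary grouping would call. With 10 splits the share cannot be under 0.05.

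Of 46 NF-kB target genes, 25 rose with a compound described as an inhibitor of a kinase upstream of NF-kB, although the list was not called with an estimated correlation (adjusted p = 0.0603). In libraries thinned to one total the median log2 fold change was 0.407 (bootstrap interval 0.262 to 0.632). Fold changes were already scaled by library total, so thinning could hardly move it. Thinning does not test what made the inhibitor libraries smaller, which cannot be told apart from the treatment. Members shared with other lists do not account for the rise. The 40 members in no other list had a median of 0.406, with 21 that rose and 2 that fell (camera p = 5.23e-14, and p = 0.0102 with an estimated correlation, neither adjusted). A candidate explanation that stays open is a change in the stability of mRNAs with AU-rich 3' UTRs. The 30 members without an AU-rich nonamer had a median of 0.316 (bootstrap interval 0.0858 to 0.475, too wide to decide) and the 16 with it 0.937 (permutation of genes, p = 0.00206), although across all other genes those with the nonamer differed from those without by 0.00415 (permutation of genes, p = 0.692) within classes of 3' UTR length. These intervals and p treat genes as independent. Whether the rise comes from IRAK4, from another target of the compound or from stress was not tested, since there was 1 compound at 1 labelled dose.

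For the fall of SR protein genes with the rise of CLK genes, the SR median was -0.656 and the CLK median 1.3 in thinned libraries. Fold changes were already scaled by library total, so thinning does not test what made the inhibitor libraries smaller. Random lists matched on abundance and gene length, 10000 in number, had medians with a 2.5th percentile of -0.115, against -0.657 for the SR list. Core spliceosome and hnRNP genes had a median above that of the SR genes by 0.54 (permutation of genes, p = 1e-05). That p is the smallest that 100000 permutations can give, treats genes as independent and does not measure the spread between cultures. Matched genes and other splicing genes thus did not fall as far. The SR list was chosen after the result was seen, so a difference was set in advance. Neither comparison is an independent test of a trend with abundance or gene length or of a general fall of splicing genes. An effect of the compound on CLK kinases was not tested, since CLK activity and SR phosphorylation were not measured. A change of isoforms that hold the amplified part of these transcripts, in place of a change of mRNA level, stays open, since the amplicon positions were not used here.

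For the fall of DNA replication genes, the median in thinned libraries was -0.747 (camera adjusted p = 7e-39), with the same limit of thinning. A lower share of cycling cells in every phase predicts a like fall of mitotic genes if both sets lose mRNA at like rates, which was not measured. The median of the replication genes lay below that of the mitotic genes by a difference of -0.413 (permutation of genes, p = 1e-05). That p is the smallest that 100000 permutations can give, treats genes as independent and does not measure the spread between cultures. The estimated correlation between genes was 0.143 in the replication list and 0.185 in the mitotic list. Replication-dependent histone genes had a median of -0.26, near the -0.313 of the mitotic genes. The difference therefore does not decide this explanation. A general fall of short-lived mRNAs predicts a fall of the immediate early genes. Their median was 0.471 (bootstrap interval over genes 0.139 to 0.791), and 0.199 with a minimum of 10 CPM. Growth factors and stress induce these genes, so their rise cannot show that other short-lived mRNAs did not fall. Of the fixed list of short-lived transcription regulators, 7 rose and 2 fell. Its median was -0.0254 (-0.169 to 0.369, and from -0.0185 to 0.0597 when single libraries were left out), against -0.727 for the replication genes. It shares MYC, MCL1 and IER5 with the immediate early list. Whether the compound acts on the transcription of the G1/S genes was not tested. Cell cycle phases were not measured, so a shift of cells between phases within 4 h stays open. A lower share of cycling cells and a general fall of short-lived mRNAs stay open as well.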
